A study of Mus musculus with 24 samples.

How the data were processed

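Dorsal and ventral hippocampi were frozen on dry ice and RNA was isolated with a column kit that yields DNA and RNA, per the labels' protocols. Libraries were made with a stranded mRNA kit and sequenced as single-end reads of 150 bp on a HiSeq2500 over 3 lanes, per the labels' protocols. The submitters' processing notes name TopHat2 2.1.0, Cufflinks, Cuffdiff 2.2.1.3 and the genome builds mm10 and GRCm38, which are names of 1 mouse assembly, and give no role for any of them. The authors deposited 1 table of raw read counts for 51912 Ensembl genes with 1 column per library. The tool that counted the reads, its strand setting, its treatment of multi-mapped reads and the annotation release are not given in the sources used here. Of the gene identifiers, 51719 were found in GENCODE release M21 (GRCm38), which gave symbols, strand and coordinates, and 193 were not.

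Groups came from the labels: sire treatment, sex and region, with the letter in each title as the replicate, and all 24 columns were matched to a library. The deposited counts were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): TMM normalization, the filterByExpr filter by group, and the robust two-sided quasi-likelihood F test, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Each region was fitted apart with 1 mean per group of sire treatment and sex, 19130 dorsal and 19224 ventral genes passing the filter, and the comparisons of regions used 1 fit of all 24 libraries (19849 genes). The common biological coefficient of variation was 0.160 in the dorsal, 0.118 in the ventral and 0.140 in the joint fit. CPM values were computed from the counts and the TMM-scaled library sizes. The 40 gene lists, which cover signalling pathways, stress responses, cell types and neighbouring tissues, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry.

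The gene lists, the comparisons, the settings to be varied and the rule for naming genes were set before the data were examined. Genes were named from those with the smallest p-values past the threshold in each direction, and not all of these were named. The pool held up to 15 genes for sire treatment over both sexes and up to 8 for the other comparisons. Also open to naming were list members with the 3 smallest p-values or past the threshold, and the cholinergic lists. So were genes past the threshold in 2 or more treatment comparisons. Where fewer than 10 genes passed, the 10 with the smallest p could be named too, said not to pass. Cdc42ep1, Pdlim2 and Klhl14 were named for the region difference in treatment in this way. Predicted genes without a symbol of their own (Gm-numbered, Rik and pseudogene models) were counted and left out of the ranking.

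The dorsal and the ventral library of 1 title prefix come from 1 animal, so they pair. The deviations of the 12 pairs from their group means correlated with a median r of 0.29 (range -0.15 to 0.71), and 8 were over 0.1. In 8 of the 12, the dorsal library correlated better with its own ventral library than with the others of its group. Those of saline-sired males A and B and saline-sired females A and C did not. The settings varied as planned were DESeq2-style size factors, no low-count filter, a non-robust fit, the DESeq2 1.42.0 Wald test, replicate or animal blocks, an additive model, the spread of all 24 libraries, other list tests and leaving out each replicate in turn (both libraries of an animal in the joint fit). Chosen after seeing the data were the fits without noncoding genes opposite coding genes, with the antisense ratio as a covariate, and with the choroid plexus level as a covariate. The antisense ratio was the summed count of 626 noncoding genes over that of the 562 coding genes on the opposite strand. Host genes had a mean of at least 50 CPM, and antisense genes a mean under 0.05 of that of the host. Among the coding genes that the text names as results, Slc15a3 (1541 bp), Chrnb2 (1365 bp), Hspa1a (564 bp) and Dbp (539 bp) had the most exon opposite another coding gene.

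The procedure was tested on simulated counts with the libraries' own means, spread and depth and 200 changed genes per comparison. The changed genes were drawn only from those above a floor of mean CPM, so the shares called do not apply to low genes. At a 2-fold change, 86.6% of changed genes were called in the dorsal and 98.5% in the ventral comparison over both sexes, 83.6% and 79.1% in males, and 47.8% and 77.6% for the difference between the sexes. A simulated list of 20 raised genes was found by camera in 12 of 12 comparisons and an unchanged list in 0 of 12. Genes and libraries were simulated independently, so this does not test camera on genes that vary together. Genes that had not been changed made up 3.17% to 8.26% of the calls per comparison. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No library was left out of the comparisons.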

Results

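RNA was sequenced from the dorsal and the ventral hippocampus of 12 C57BL/6J mice, the offspring of males (sires) treated chronically with nicotine or with saline. The 24 libraries formed 8 groups of 3: sire treatment by sex of the offspring by hippocampal region, with both regions taken from each animal. The counts summed to about 32049800 and 47486500 per library, with a median of 39578800. Between 23632 and 25543 genes had a count in each library. Xist, the X-inactivation transcript, and the Y-linked gene Ddx3y matched the labelled sex in all 24 libraries. Ttr, the transthyretin transcript that choroid plexus makes in large amounts, ranged from 25.2 to 5204 CPM (counts scaled to a library size of 1e6) among libraries. The number in the library titles differed between all 4 combinations of sire treatment and sex, and the labels do not say what it marks, so it cannot be told apart from those groups. Fold changes below are log2 values, nicotine-sired over saline-sired unless another contrast is named, each with its standard error (SE) and 3 libraries per group. The SEs and p-values measure the spread between libraries within groups. The sires were treated, and the title number may mark a sire or litter. The 3 libraries of a group may therefore not be 3 independent replicates of the sire treatment.

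The first comparison asked which hippocampal genes differ between offspring of nicotine-treated and saline-treated sires, averaged over the sexes. In the dorsal hippocampus, the known glucocorticoid target Tsc22d3 was lower in nicotine-sired offspring, with a log2 fold change of -0.64 ± 0.08. It encodes the leucine zipper protein GILZ (ENSMUSG00000031431, chromosome X, 140539528 to 140600659; GRCm38/mm10, here and below). The serum and glucocorticoid kinase gene Sgk1 (ENSMUSG00000019970, chromosome 10, 21882184 to 21999903) was lower as well, at -0.62 ± 0.09. The arrestin-domain gene Arrdc2 (-0.69 ± 0.09), the hypoxia-inducible factor gene Hif3a (-1.17 ± 0.16), the glycosyltransferase gene Galnt15 (-1.09 ± 0.16) and the xanthine dehydrogenase gene Xdh (-0.90 ± 0.12) were lower too. The chaperone genes Pdia6 (-0.38 ± 0.05) and Hspa1b (-0.66 ± 0.10) fell, and the cell adhesion gene Mcam (0.62 ± 0.09) rose. Tmem254a, Tmem254b and Tmem254c were higher by 0.36 ± 0.06, 0.35 ± 0.06 and 0.33 ± 0.05. These near-identical copies may share reads and are uncertain, as is Hspa1b, whose copy is Hspa1a. In refits without 1 replicate, the calls of Tmem254a, Tmem254b and Tmem254c ended in 11 of 12 each, that of Hspa1b in 10 and those of the other genes above in 7 to 9. The treatment difference of Sgk1, Arrdc2, Xdh, Pdia6 and Hspa1b differed between the sexes, as given further on, so their averages over the sexes do not describe each sex. Of 24 heat shock and unfolded protein genes, 2 were lower over all genes tested and 21 were lower adjusted over the list alone. Their median was -0.25, with a camera adjusted p = 0.0217 with an estimated correlation. Of 21 glucocorticoid and stress axis genes, 2 were lower over all genes and 8 adjusted over the list alone (median -0.13, camera adjusted p = 0.00975 with an estimated correlation). Both lists also differed between the sexes in their treatment difference (medians 0.74 and 0.41, camera adjusted p = 0.0234 each with an estimated correlation), so these averages do not describe each sex either. Blood cell markers had a median of 0.63: edgeR called 0 of 7 over all genes, 5 were higher and 2 lower adjusted over the list alone, 7 had an unadjusted p under 0.05 and DESeq2 called 5 (camera adjusted p = 0.518 with an estimated correlation).

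In all, edgeR's quasi-likelihood test called 15 of 19130 dorsal genes, 5 higher and 10 lower, and 2062 had an unadjusted p under 0.05. The named genes above had edgeR adjusted p-values from 0.0213 (Arrdc2) to 0.0473 (Tmem254a). Camera with its preset correlation called 17 of 40 gene lists, 10 higher and 7 lower. The chaperone and the glucocorticoid lists were called with an estimated correlation too, and the other 15 had adjusted p = 0.335 to 0.737 with an estimated correlation. The count was 0 without nicotine-sired male A or B or saline-sired female B or C or saline-sired male B, 1 without nicotine-sired male C, 2 without saline-sired male A and 5 without nicotine-sired female C. DESeq2 called 203 genes, edgeR without a low-count filter 55, edgeR with the spread of all 24 libraries 61, an additive model 0, and edgeR with the antisense ratio given with the ventral values as a covariate 1.

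In the ventral hippocampus, the same glucocorticoid targets were lower in nicotine-sired offspring, Tsc22d3 (-0.77 ± 0.06) and Sgk1 (-0.54 ± 0.08). So were the stress-induced gene Ddit4 (-0.44 ± 0.06), the glucocorticoid receptor co-chaperone gene Fkbp4 (-0.29 ± 0.05) and the metallothionein gene Mt2 (-0.55 ± 0.12). Arrdc2 (-0.76 ± 0.07), Hif3a (-1.12 ± 0.14) and Galnt15 (-1.08 ± 0.13) fell as well, and so did the NF-kappa-B inhibitor gene Nfkbia (-0.44 ± 0.06), the transcription factor gene Klf15 (-0.48 ± 0.06) and the choline kinase gene Chka (-0.33 ± 0.04). Mt2 was not called in 9 of 12 refits without 1 replicate (-0.50 to -0.59), those without nicotine-sired female A or B, nicotine-sired male B or any saline-sired animal. Of 21 glucocorticoid and stress axis genes, 5 were lower over all genes and 9 were lower and 1 higher adjusted over the list alone (median -0.20, camera adjusted p = 0.00527 with an estimated correlation). Of 24 heat shock and unfolded protein genes, 10 were lower over all genes and 21 adjusted over the list alone, among them Hspa1a (-0.76 ± 0.10), Hspb1 (-0.76 ± 0.13), Hspa5 (-0.38 ± 0.06) and Pdia6 (-0.34 ± 0.05). That list had a camera adjusted p = 0.0631 with an estimated correlation, and Hspa1a is uncertain because its copy Hspa1b may share reads. Higher in nicotine-sired offspring were the endothelial receptor genes Kdr (0.52 ± 0.07) and Tek (0.40 ± 0.07), the transferrin receptor gene Tfrc (0.50 ± 0.07), Itm2a (0.40 ± 0.06) and the organic anion transporter gene Slco1a4 (0.43 ± 0.06). Of 18 endothelial and pericyte markers, 4 rose and 1 fell over all genes, 5 and 1 adjusted over the list alone, and the list's camera adjusted p = 0.422 with an estimated correlation. The treatment difference of Sgk1, Fkbp4, Hspa1a, Hspb1, Hspa5, Pdia6, Tfrc, Itm2a and Slco1a4 and of the heat shock list differed between the sexes in this region too.

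The transporter genes Slc16a4 (1.46 ± 0.18), Slc15a3 (0.99 ± 0.14) and Slc6a6 (0.32 ± 0.05) were also higher in the ventral hippocampus of nicotine-sired offspring. Hemoglobin transcripts were higher, Hba-a2 (0.56 ± 0.08) and Hbb-bs (0.42 ± 0.08), where near-identical globin copies may share reads. Further, 4 of 7 blood cell markers rose over all genes and 5 adjusted over the list alone (camera adjusted p = 0.0708 with an estimated correlation). All 22 choroid plexus markers had a positive log2 fold change with a median of 1.55. Of these, 0 passed edgeR's test over all genes, 18 passed adjusted over the list alone, 18 had an unadjusted p under 0.05 and DESeq2 called 11 (camera adjusted p = 0.422 with an estimated correlation). Their mean level was 4.16 and 4.42 log2 CPM in nicotine-sired females B and C and at most 1.37 in the other ventral libraries. Noncoding genes opposite coding genes made up part of the higher calls, among them Grin1os (2.76 ± 0.30), Chn1os3 (2.55 ± 0.27), Chn1os1 (2.27 ± 0.32) and Rapgef4os2 (3.25 ± 0.46). They are uncertain because the strand setting of the deposited counting is not stated, as is Slc15a3, with 1541 bp of exon opposite the coding gene Tmem132a. Antisense counts, as a percentage of the counts of their host genes (the antisense ratio), lay between 0.370 and 0.480% in the ventral libraries of nicotine-sired males and were at most 0.310% in the other ventral libraries.

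Overall counts in the ventral hippocampus were 337 genes of 19224 by edgeR, 212 higher and 125 lower. The named genes had edgeR adjusted p-values from 8.7e-05 (Tsc22d3) to 0.0395 (Mt2). Of the 10 dorsal genes called lower, 10 were also called lower in the ventral hippocampus of the same animals, where independent lists would share 0.0661. Camera with its preset correlation called 10 of 40 lists, 6 higher and 4 lower, of which the glucocorticoid list was called with an estimated correlation. The other 9 had adjusted p = 0.0631 to 0.972 with an estimated correlation. The count was 176 without saline-sired female C, 185 without nicotine-sired female B, 196 without saline-sired male C and 215 without nicotine-sired female C. DESeq2 called 681 genes, edgeR without a low-count filter 560, with the spread of all 24 libraries 206 and with an additive model 216. EdgeR called, without the noncoding genes opposite coding genes 191 genes, with the choroid plexus level as a covariate 166 and with the antisense ratio as a covariate 1. Of the 337 genes, 96 were called again with the choroid plexus level and 0 with the antisense ratio.

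Within males, the dorsal hippocampus of nicotine-sired animals had lower levels of chaperone transcripts than that of saline-sired animals. Hspa5, which encodes the endoplasmic reticulum chaperone BiP (ENSMUSG00000026864, chromosome 2, 34771970 to 34777547), fell by a log2 value of 0.997 ± 0.10, from 588 ± 38.4 to 295 ± 16.8 CPM (SD, n = 3). Of 24 heat shock and unfolded protein genes, 20 were lower over all genes and 21 adjusted over the list alone (camera adjusted p = 0.00275 with an estimated correlation). They included Pdia6 (-0.91 ± 0.07), Hsp90b1 (-0.84 ± 0.08), Hyou1 (-0.74 ± 0.06), Sdf2l1 (-1.25 ± 0.12) and Stip1 (-0.64 ± 0.06). The glucocorticoid targets Sgk1 (-1.13 ± 0.12) and Tsc22d3 (-0.93 ± 0.12) were lower. Of 21 glucocorticoid and stress axis genes 6 were lower over all genes and 10 adjusted over the list alone (camera adjusted p = 0.00275 with an estimated correlation). Arrdc2 (-1.29 ± 0.13) and Xdh (-1.70 ± 0.17) and the imprinted gene Peg10 (-1.36 ± 0.14) fell. Lcn2, the secreted iron-siderophore binding protein lipocalin 2 (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252), averaged 20.1 ± 10.6 CPM in saline-sired males and 0.135 ± 0.0310 CPM in nicotine-sired males (SD, n = 3). The cold-induced RNA-binding protein genes Rbm3 (1.07 ± 0.09) and Cirbp (0.99 ± 0.09), the circadian transcription factor gene Dbp (1.01 ± 0.11), the ribonucleoprotein gene Hnrnpdl (0.64 ± 0.08) and the vessel-associated genes Tfrc (0.99 ± 0.10), Itm2a (0.73 ± 0.08) and Gkn3 (1.85 ± 0.24) were higher. The brain endothelial transporter genes Mfsd2a (-0.76 ± 0.13) and Slc2a1 (-0.52 ± 0.11) were lower. Mfsd2a was not called without nicotine-sired male A or B or saline-sired male B or C (-0.68 to -0.77), and Slc2a1 without any 1 of the 6 males or saline-sired female B (-0.43 to -0.57). Of 18 endothelial and pericyte markers 3 were higher over all genes and 4 adjusted over the list alone (camera adjusted p = 0.425 with an estimated correlation).

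The dorsal male comparison gave 341 genes by edgeR, 90 higher and 251 lower. The named genes had edgeR adjusted p-values from 2.7e-04 (Pdia6) to 0.0318 (Slc2a1). The count was 87 without nicotine-sired male A, 99 without nicotine-sired male B, 105 without saline-sired male B and 113 without nicotine-sired male C. It was 116 without saline-sired male A, 124 without saline-sired male C, 211 without saline-sired female B and 624 without nicotine-sired female A. DESeq2 called 878 genes and edgeR with the antisense ratio as a covariate 152.

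In the ventral hippocampus of males, 21 of 24 heat shock and unfolded protein genes were lower in nicotine-sired animals, and as many adjusted over the list alone (camera adjusted p = 0.00309 with an estimated correlation). Among them were Hspa5 (-0.96 ± 0.09), Pdia6 (-0.85 ± 0.07), Stip1 (-0.69 ± 0.06), Hsph1 (-0.71 ± 0.07) and Hyou1 (-0.65 ± 0.06). Tsc22d3 (-0.87 ± 0.09), Sgk1 (-0.98 ± 0.12) and Arrdc2 (-1.03 ± 0.10) fell. Of 21 glucocorticoid and stress axis genes 5 were lower over all genes and 11 adjusted over the list alone, with 1 higher (camera adjusted p = 0.00309 with an estimated correlation). Lcn2 averaged 15.8 ± 5.28 CPM in saline-sired and 0.0399 ± 0.0288 CPM in nicotine-sired males (SD, n = 3). Higher in nicotine-sired males were Rbm3 (1.07 ± 0.12) and Cirbp (0.91 ± 0.08), the vessel-associated genes Tfrc (1.18 ± 0.09), Itm2a (0.91 ± 0.08), Slco1a4 (0.89 ± 0.08) and Gkn3 (2.71 ± 0.26), the oligodendrocyte gene Opalin (0.998 ± 0.10) and the transcription factor gene Sox21 (1.09 ± 0.12). The brain endothelial genes Ly6a (-0.88 ± 0.14), Mfsd2a (-0.76 ± 0.13), Ly6c1 (-0.63 ± 0.12) and Slc2a1 (-0.50 ± 0.10) were lower, and Slc2a1 was not called without saline-sired male B (-0.44). Of 18 endothelial and pericyte markers 4 were higher and 1 lower over all genes, 9 and 1 adjusted over the list alone (camera adjusted p = 0.303 with an estimated correlation). Between the dorsal and the ventral hippocampus of these males, 42 genes were called higher in both and 124 lower in both, where independent lists would share 1.63 and 3.54. Both regions came from the same animals.

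The ventral male comparison gave 617 genes by edgeR, 349 higher and 268 lower. The named genes had edgeR adjusted p-values from 1.0e-05 (Lcn2) to 0.0125 (Slc2a1). The count was 284 without saline-sired male C, 309 without nicotine-sired male C, 338 without saline-sired male A and 381 without saline-sired male B. With the antisense ratio as a covariate edgeR called 1 gene, and 0 of the 617 were called again. Hspa5 went from -0.96 ± 0.09 to -0.96 ± 0.28.

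**Figure D1:**
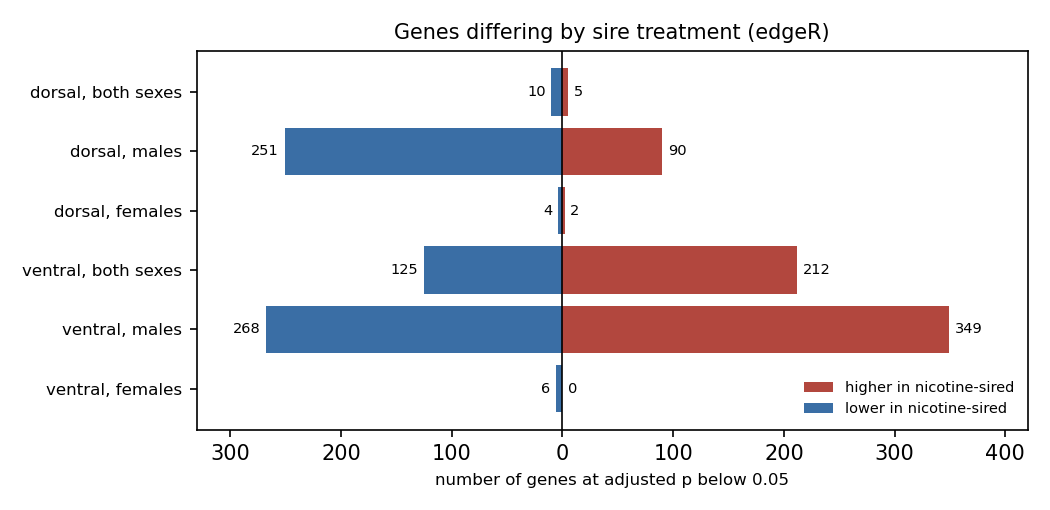
Number of genes with an edgeR adjusted p under 0.05 for each sire treatment comparison (x axis, number of genes, lower calls to the left and higher calls to the right of 0; y axis, comparison). The bars for males reach 251 lower and 90 higher genes in the dorsal and 268 lower and 349 higher genes in the ventral hippocampus, those for females at most 6.

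Within females, few genes passed. In the dorsal hippocampus of nicotine-sired females Rbm3 (ENSMUSG00000031167, chromosome X, 8138975 to 8145880) was lower, at -0.77 ± 0.09, the microtubule-associated protein gene Eml2 (-0.50 ± 0.07) was lower and the Cdc42 effector gene Cdc42ep1 (0.63 ± 0.09) was higher. Their edgeR adjusted p-values were 0.0164, 0.0400 and 0.0400. In the ventral hippocampus Tsc22d3 (-0.67 ± 0.09), Cirbp (-0.59 ± 0.08) and Eml2 (-0.50 ± 0.08) were lower, with edgeR adjusted p-values of 0.0183, 0.0183 and 0.0313. In refits without 1 replicate, the dorsal calls ended in 3 of 12 for Rbm3, 7 for Eml2 and 7 for Cdc42ep1. The ventral calls ended in 3 for Tsc22d3, 4 for Cirbp and 7 for Eml2. Of the dorsal genes that did not pass, Myo1e (0.72 ± 0.11), Peg10 (0.83 ± 0.14), Cirbp (-0.56 ± 0.09) and Dbp (-0.61 ± 0.11) had edgeR adjusted p-values of 0.0820, 0.0826, 0.105 and 0.132. Ventral genes that did not pass included Vwa5b1 (1.16 ± 0.19), Pla2g5 (2.03 ± 0.34), Cfap206 (1.46 ± 0.25), Dynlrb2 (1.87 ± 0.32) and Stk39 (0.36 ± 0.06), each with an edgeR adjusted p of 0.0589. Of 24 heat shock and unfolded protein genes 0 passed edgeR's test in either region of females, 3 dorsal and 9 ventral genes had an unadjusted p under 0.05, and DESeq2 called 0 and 2. Choroid plexus markers had a median log2 fold change of 2.52 in the dorsal and 3.04 in the ventral hippocampus of females, with a camera adjusted p = 0.719 and 0.243 with an estimated correlation. EdgeR called 0 of the 22 in either region, 0 dorsal and 21 ventral markers had an unadjusted p under 0.05, 0 and 21 passed adjusted over the list alone, and DESeq2 called 0 and 18. The ventral difference came from nicotine-sired females B and C, with a mean marker level of 4.16 and 4.42 log2 CPM. Nicotine-sired female A had 1.01, within the 0.563 to 1.37 of saline-sired females. All 7 blood cell markers had a positive log2 fold change in the ventral hippocampus of females. Of these, 0 passed edgeR's test over all genes and 7 passed adjusted over the list alone. All 7 had an unadjusted p under 0.05, DESeq2 called 5, and the list's camera adjusted p = 0.0424 with an estimated correlation.

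EdgeR called 6 genes in each region of females, 2 higher and 4 lower in the dorsal and 0 higher and 6 lower in the ventral hippocampus. Of all genes tested, 2547 and 2668 had an unadjusted p under 0.05, and DESeq2 called 284 and 283. On simulated counts with the same depth and spread, a change of 2-fold was called in 76.1% of changed genes in the dorsal female comparison. In the ventral female comparison it was 82.1%. There 200 genes, none of low mean CPM, were changed at once. The adjusted threshold is stricter where fewer genes change, so these shares do not apply to few changed genes. The dorsal count was 0 without nicotine-sired female C or saline-sired female B or C, 1 without nicotine-sired female B, 3 without saline-sired female A or saline-sired male B and 12 without saline-sired male C. The ventral count was 0 without nicotine-sired female B or saline-sired female C, 2 without saline-sired female B and 11 without saline-sired female A or saline-sired male C. It was 51 without nicotine-sired male A and 114 without nicotine-sired female A.

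The next comparison tested whether the sire treatment difference itself differed between the sexes, as the female minus the male log2 fold change. Chaperone genes had a higher treatment difference in females than in males, Pdia6 (1.05 ± 0.10), Hsp90b1 (1.09 ± 0.11), Hyou1 (0.94 ± 0.09) and Stip1 (0.93 ± 0.09) in the dorsal and Hspa5 (1.16 ± 0.13), Pdia6 (1.01 ± 0.10), Hsp90b1 (0.94 ± 0.10) and Stip1 (0.96 ± 0.09) in the ventral hippocampus. Of 24 heat shock and unfolded protein genes, 16 dorsal and 17 ventral genes passed this test in that direction, 20 and 21 adjusted over the list alone (camera adjusted p = 0.0234 and 0.0119 with an estimated correlation). The imprinted gene Peg10 (2.19 ± 0.19) had the same direction in the dorsal hippocampus. The cold-induced and clock-related genes had the opposite direction, Rbm3 (-1.84 ± 0.13), Cirbp (-1.55 ± 0.13) and Dbp (-1.62 ± 0.15) in the dorsal and Rbm3 (-1.74 ± 0.17) and Cirbp (-1.5 ± 0.11) in the ventral hippocampus. Rbm3 averaged 37.7 ± 2.26 CPM in the dorsal hippocampus of saline-sired males, 79.5 ± 2.98 in nicotine-sired males, 66.3 ± 7.82 in saline-sired females and 38.7 ± 2.99 in nicotine-sired females (SD, n = 3). Eml2 (-0.996 ± 0.10), Tfrc (-1.31 ± 0.14) and Gkn3 (-2.47 ± 0.33) in the dorsal hippocampus and Eml2 (-0.93 ± 0.11), Tfrc (-1.36 ± 0.13), Gkn3 (-3.52 ± 0.34), Itm2a (-1.03 ± 0.11), Opalin (-1.14 ± 0.14) and Slco1a4 (-0.92 ± 0.12) in the ventral hippocampus also had a lower treatment difference in females than in males. Sgk1, Arrdc2, Xdh and Hspa1b had a higher one in the dorsal hippocampus, at 1.04 ± 0.17, 1.21 ± 0.18, 1.61 ± 0.24 and 1.09 ± 0.20.

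EdgeR called 428 dorsal genes for this difference between the sexes, 266 higher and 162 lower, and 205 ventral genes, 107 higher and 98 lower. The named genes had edgeR adjusted p-values from 5.3e-05 (Rbm3) to 0.0206 (Hspa1b) in the dorsal and 4.3e-05 (Cirbp) to 0.00152 (Slco1a4) in the ventral hippocampus. Across the 14094 genes with a mean over 2 CPM, which are not independent replicates, the male and female log2 fold changes had a Pearson r of -0.31 and a Spearman rho of -0.25 in the dorsal and 0.00578 and 0.0314 in the ventral hippocampus. The dorsal count was 76 without saline-sired female B, 92 without nicotine-sired female C, 94 without nicotine-sired male C and 116 without nicotine-sired male A. It was 121 without saline-sired male B, 142 without saline-sired male A, 241 without saline-sired female A and 273 without nicotine-sired male B. It was also 282 without nicotine-sired female B and 837 without nicotine-sired female A. The ventral count was 84 without saline-sired male A, 88 without nicotine-sired female B, 91 without nicotine-sired male C and 93 without saline-sired male B. It was 96 without saline-sired male C, 102 without nicotine-sired male B, 116 without saline-sired female C and 119 without nicotine-sired female C. It was also 124 without saline-sired female B and 463 without nicotine-sired male A. DESeq2 called 1289 dorsal and 547 ventral genes, edgeR with the choroid plexus level as a covariate 236 and 112, and with the antisense ratio as a covariate 3 in the ventral hippocampus.

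**Figure D2:**
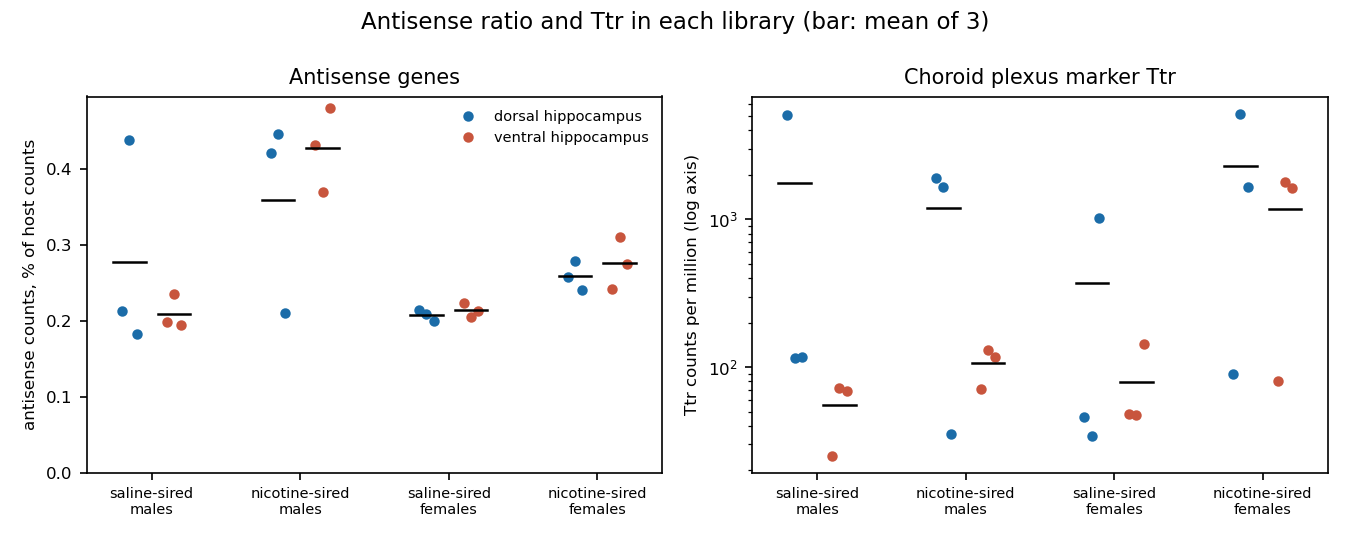
Antisense counts as a percentage of the counts of their host genes (left, y axis) and CPM of Ttr (right, y axis on a log scale) in each library, by sire treatment and sex (x axes), with dorsal libraries in blue, ventral libraries in red and bars at the mean of 3. Both measures vary within groups in the dorsal hippocampus.

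**Figure D3:**
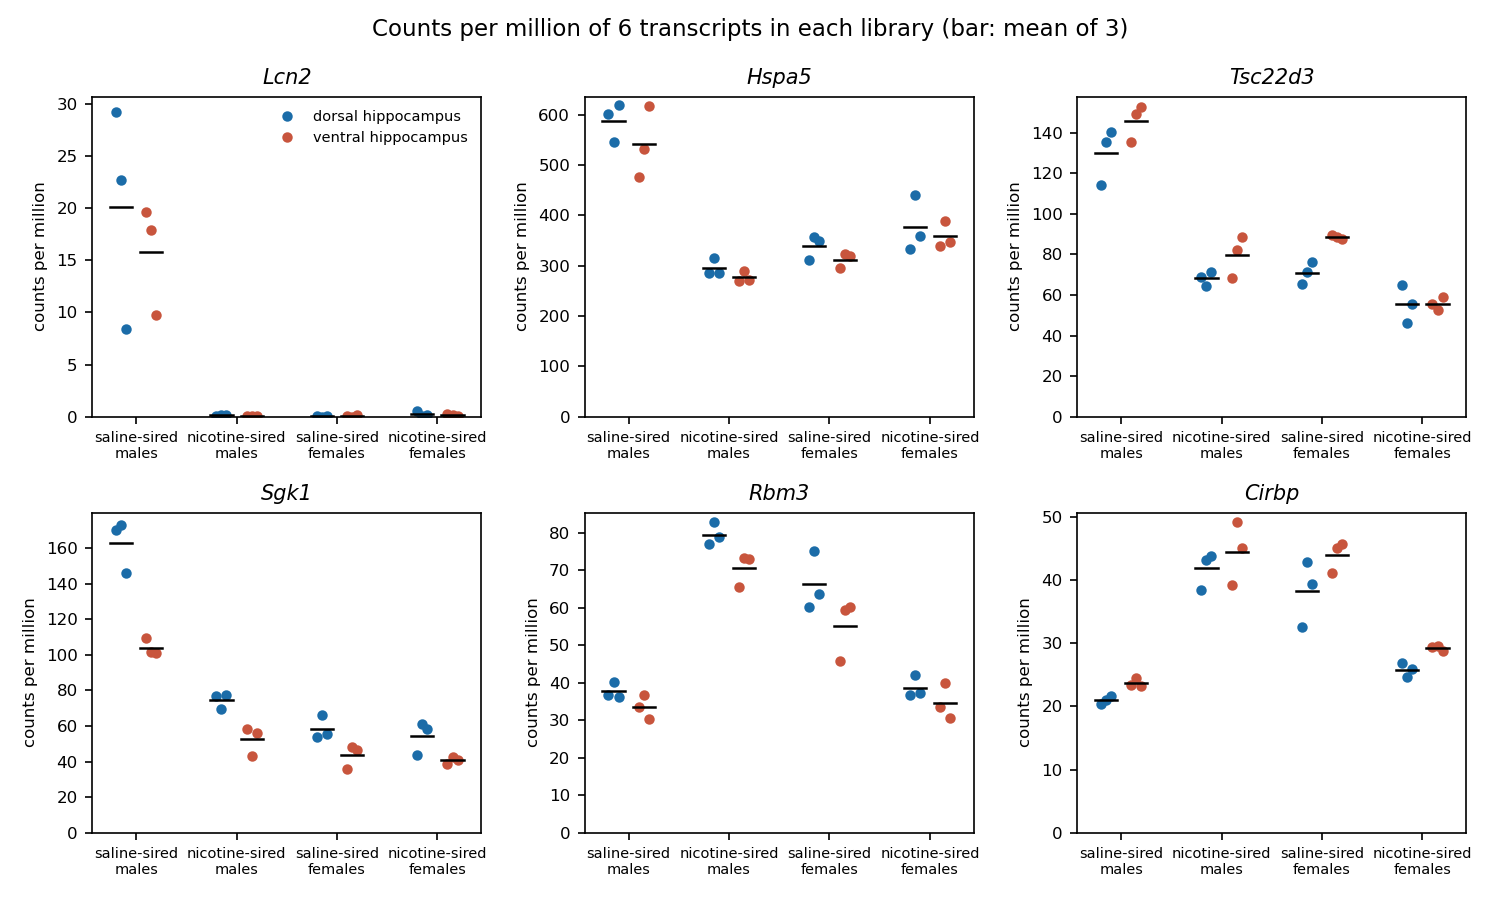
CPM (y axes) of 6 transcripts in each library, by sire treatment and sex (x axes), with dorsal libraries in blue, ventral libraries in red and bars at the mean of 3. Lcn2 lies between 8.43 and 29.2 CPM in the 6 libraries of saline-sired males and at or under 0.537 CPM in the other 18 libraries.

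Because nicotine acts on nicotinic acetylcholine receptors, their subunits and other cholinergic genes were listed in advance. None of the nicotinic subunit genes passed edgeR's test for sire treatment in the dorsal (0 of 10) or the ventral hippocampus (0 of 11) over both sexes. Of these, 0 and 0 had an unadjusted p under 0.05, and DESeq2 called 0 and 0. Chrnb2, the beta2 subunit gene, had log2 fold changes of -0.09 ± 0.05 in the dorsal and -0.05 ± 0.05 in the ventral hippocampus. Of 18 other cholinergic signalling genes 0 passed edgeR's test in either region over both sexes. Of these, 4 dorsal and 3 ventral genes had an unadjusted p under 0.05, and DESeq2 called 0 and 1. The camera adjusted p of the nicotinic list was 0.574 in the dorsal and 0.933 in the ventral hippocampus, and that of the other cholinergic list 0.604 and 0.933. Within each sex and for the difference between the sexes, edgeR also called 0 genes of these lists in either region. There 0 to 3 nicotinic and 3 to 7 other cholinergic genes per comparison had an unadjusted p under 0.05, and DESeq2 called 0 to 1 and 0 to 2.

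Whether the sire treatment difference differed between the regions was tested as the ventral minus the dorsal log2 fold change, averaged over the sexes. The genes with the smallest p-values were Cdc42ep1 (-0.38 ± 0.10), Pdlim2 (-0.48 ± 0.12) and Klhl14 (1.92 ± 0.50), and none passed, with edgeR adjusted p-values of 0.881 each. EdgeR called 0 of 19849 genes, 945 had an unadjusted p under 0.05, and DESeq2 called 0. On simulated counts with 200 genes, none of low mean CPM, changed at once, a change of 2-fold in this difference was called in 94.0% of changed genes. A change of 1.5-fold was called in 70.1%. The adjusted threshold is stricter where fewer genes change, so these shares do not apply to few changed genes. The simulation did not keep the pairing of regions within animals. With the animal as a block edgeR called 0.

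The ventral and the dorsal hippocampus of saline-sired offspring differed in many genes, given here as ventral over dorsal. Known ventral markers were higher in the ventral hippocampus, 7 of 9 over all genes and 8 adjusted over the list alone. They included the nuclear receptor gene Nr2f2 (1.503 ± 0.23), the neuropeptide gene Grp (1.65 ± 0.27), the thyrotropin-releasing hormone receptor gene Trhr (2.01 ± 0.42) and the decorin gene Dcn (2.1 ± 0.47). Of 4 dorsal markers 1 was lower over all genes and 2 adjusted over the list alone, with Lct (-2.18 ± 0.43), which is also a dentate marker (camera adjusted p = 0.523 with an estimated correlation). Without saline-sired female A, Dcn (1.87) was not called. Dentate granule cell markers were lower, 10 of 12 over all genes and 11 adjusted over the list alone, with Stxbp6 (-0.73 ± 0.11) and the dynorphin precursor gene Pdyn (-1.02 ± 0.17). So were 6 of 8 CA2 pyramidal markers, as many adjusted over the list alone, with the vasopressin receptor gene Avpr1b (-2.74 ± 0.54) and the adenylate cyclase gene Adcy1 (-0.73 ± 0.10). Of 20 oligodendrocyte and myelin markers 19 were lower, as many adjusted over the list alone, with the myelin genes Mobp (-0.79 ± 0.12), Mog (-0.65 ± 0.11) and Mbp (-0.62 ± 0.12). With an estimated correlation, the ventral, dentate, CA2 and myelin lists each had a camera adjusted p = 0.0715.

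Of 44 imprinted genes 13 were higher and 1 lower in the ventral hippocampus, 13 and 2 adjusted over the list alone, with Plagl1 (1.35 ± 0.19) and Nnat (1.27 ± 0.18) (camera adjusted p = 0.120 with an estimated correlation). Of 18 interneuron markers 5 were higher, 6 higher and 1 lower adjusted over the list alone, with the somatostatin gene Sst (0.46 ± 0.09) (camera adjusted p = 0.164 with an estimated correlation). Among 19 cholinergic genes other than nicotinic subunits 6 were higher and 2 lower, as many adjusted over the list alone, with Ly6h (0.67 ± 0.08) higher and the muscarinic receptor gene Chrm3 (-0.59 ± 0.09) lower (camera adjusted p = 0.0715 with an estimated correlation). The nicotinic subunit gene Chrnb2 (0.17 ± 0.05) was higher, at an edgeR adjusted p of 0.0202, and was not called without saline-sired female A, female B or male A (0.15, 0.16 and 0.16). Of the neighbouring tissues, 3 of 12 thalamus markers were higher and 2 lower, as many adjusted over the list alone, the protein kinase C gene Prkcd (-1.72 ± 0.28) among the lower ones. Of 12 striatum markers 3 were higher, 3 higher and 3 lower adjusted over the list alone. Choroid plexus markers had a median of -2.38, and of 22 edgeR called 0, 15 had an unadjusted p under 0.05 and DESeq2 called 14. The camera adjusted p of these 3 lists was 0.823, 0.752 and 0.625 with an estimated correlation. The neurotrophin gene Bdnf (-0.65 ± 0.10) was lower, as was the kinesin gene Kif13b (-0.78 ± 0.08), while the huntingtin-associated protein gene Hap1 (1.04 ± 0.12) was higher. EdgeR called 2877 of 19849 genes, 1345 higher and 1532 lower, and 4435 with the animal as a block. The named genes had edgeR adjusted p-values from 2.7e-05 (Kif13b) to 0.0202 (Chrnb2). The count was 1097 without saline-sired female A, 1280 without saline-sired male B, 1638 without saline-sired female B and 1657 without saline-sired male A.

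Between females and males, averaged over the sire treatments, X-linked transcripts differed: Xist (9.94 ± 0.29) and Eif2s3x (0.57 ± 0.04) were higher in females in the dorsal hippocampus, and Xist (10.04 ± 0.31) and Eif2s3x (0.57 ± 0.04) in the ventral hippocampus. Outside the sex chromosomes, Sgk1 (-0.97 ± 0.09) and Arrdc2 (-0.77 ± 0.09) in the dorsal hippocampus and Sgk1 (-0.81 ± 0.08) in the ventral hippocampus were lower in females, with the X-linked Tsc22d3 (-0.62 ± 0.06) in the ventral hippocampus. The endothelial receptor gene Kdr was higher in females by 0.62 ± 0.09 and 0.47 ± 0.07 in the 2 regions and the oligodendrocyte gene Opalin (0.61 ± 0.07) in the ventral hippocampus. Dorsal Kdr was not called without nicotine-sired male A or C or saline-sired female A (0.59, 0.62 and 0.61). The treatment difference of Sgk1 and Arrdc2 in the dorsal and of Sgk1 and Opalin in the ventral hippocampus differed between the sexes, so their averages over the sire treatments do not describe each treatment. Outside the X and Y chromosomes, females and males differed in 346 dorsal and 419 ventral genes by edgeR when saline-sired and in 2 and 5 when nicotine-sired. EdgeR called 35 dorsal genes, 12 higher and 23 lower in females, and 56 ventral genes, 26 higher and 30 lower. The named genes had edgeR adjusted p-values from 3.4e-08 (Xist) to 0.0150 (Kdr) and 5.3e-08 (Xist) to 0.00852 (Kdr). The dorsal count was 22 without nicotine-sired male B and 23 without nicotine-sired male C. The ventral count was 29 without nicotine-sired male C, 31 without saline-sired male B, 32 without saline-sired male A and 36 without nicotine-sired female B or saline-sired male C. It was 37 without nicotine-sired female C and 125 without nicotine-sired female A. DESeq2 called 113 and 250 genes, and edgeR without a low-count filter 54 and 124.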

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

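The tests of the 3 patterns weighed here, for tissue sources (neutrophils and choroid plexus), title number, strand, genomic DNA, time of day and temperature, were chosen after the results were seen, and the bounds of the time of day and temperature tests were set with their counts already known. The splits of the samples were planned, and which animals they place together was looked up after the results were seen. Single libraries in the groups of 3 were not tested as outlying.

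The sire treatment difference differed between females and males in 428 dorsal and 205 ventral genes by edgeR's test of that difference. The female minus male differences (log2 ± SE, edgeR adjusted p-values from 5.3e-05 to 0.0488) in the dorsal hippocampus were Arrdc2 1.21 ± 0.18, Cirbp -1.55 ± 0.13, Dbp -1.62 ± 0.15, Eml2 -0.996 ± 0.10, Fkbp4 0.74 ± 0.09, Gkn3 -2.47 ± 0.33, Hnrnpdl -0.79 ± 0.11, Hsp90b1 1.09 ± 0.11, Hspa1a 0.91 ± 0.19, Hspa1b 1.09 ± 0.20, Hspa5 1.16 ± 0.14, Hspb1 1.72 ± 0.27, Hyou1 0.94 ± 0.09, Itm2a -0.84 ± 0.12, Klf15 0.62 ± 0.15, Lcn2 9.09 ± 1.31, Pdia6 1.05 ± 0.10, Peg10 2.19 ± 0.19, Rbm3 -1.84 ± 0.13, S100a8 4.10 ± 0.86, Sdf2l1 1.56 ± 0.16, Sgk1 1.04 ± 0.17, Slc2a1 0.66 ± 0.15, Stip1 0.93 ± 0.09, Tfrc -1.31 ± 0.14 and Xdh 1.61 ± 0.24. In the ventral hippocampus they were Cirbp -1.5 ± 0.11, Eml2 -0.93 ± 0.11, Fkbp4 0.59 ± 0.11, Gkn3 -3.52 ± 0.34, Hsp90b1 0.94 ± 0.10, Hspa1a 1.10 ± 0.21, Hspa5 1.16 ± 0.13, Hspb1 1.29 ± 0.27, Hsph1 0.91 ± 0.10, Hyou1 0.78 ± 0.09, Itm2a -1.03 ± 0.11, Lcn2 10.04 ± 1.11, Opalin -1.14 ± 0.14, Pdia6 1.01 ± 0.10, Rbm3 -1.74 ± 0.17, S100a8 5.93 ± 1.01, S100a9 5.18 ± 0.71, Sgk1 0.88 ± 0.17, Slco1a4 -0.92 ± 0.12, Sox21 -1.23 ± 0.17, Stip1 0.96 ± 0.09, Tfrc -1.36 ± 0.13 and Xdh 1.73 ± 0.25 (edgeR adjusted p-values from 4.3e-05 to 0.0407). The differences for Lcn2 rest on counts near 0 outside the saline-sired males. The list medians of this difference were 0.41 for the glucocorticoid and stress axis and 0.74 for heat shock and unfolded protein genes in the dorsal hippocampus, with camera adjusted p = 0.0234 and 0.0234 with an estimated correlation. In the ventral hippocampus they were 0.76 for heat shock and unfolded protein genes and 3.72 for hypothalamus and pituitary markers, with camera adjusted p = 0.0119 and 0.0392 with an estimated correlation. Of the 10 hypothalamus and pituitary markers edgeR called 0, 8 had an unadjusted p under 0.05 and DESeq2 called 3, and Prl and Gh among them were highest in 1 library, the ventral one of nicotine-sired female B (209 and 115 CPM). Prl was at most 0.238 CPM in the 6 libraries of nicotine-sired males and at least 0.843 CPM in the other 18.

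Saline-sired males differed from each of the other 3 groups in many genes outside the sex chromosomes, 90, 328 and 346 in the dorsal hippocampus, where the other pairs of groups differed in 2, 3 and 8, while in the ventral hippocampus the counts were 218, 596 and 419 against 5, 3 and 221. Neutrophils as the source of Lcn2 are argued against by their most abundant transcripts, S100a8 plus S100a9, which reached 0.0622 of the Lcn2 level in the 6 libraries of saline-sired males (1.12 against 17.9 CPM), although S100a8 (-4.31 ± 0.64) and S100a9 (-3.52 ± 0.78) in the dorsal and S100a8 (-3.44 ± 0.76) and S100a9 (-3.43 ± 0.51) in the ventral hippocampus fell with Lcn2 in nicotine-sired males (not called in 0, 10, 5 and 0 of 12 refits without 1 replicate), so a small difference in neutrophils stays open. Choroid plexus in the dissection is argued against as the whole cause between the males. Of the genes called there, 92.9% over both regions were called again with the choroid plexus level as a covariate. That level was close between saline-sired and nicotine-sired males, with means of 2.81 and 2.71 log2 CPM in the dorsal and 0.751 and 1.03 in the ventral hippocampus. The genes called for the difference between the sexes kept a median of 0.968 of their dorsal and 1.01 of their ventral log2 difference. Of these, 210 of 428 and 81 of 205 were called again (median SE 0.135 to 0.138 and 0.140 to 0.165, with 1 fewer residual degree of freedom). The kept sizes argue against choroid plexus as the whole cause of that difference. The share called again, the measure used for the males, does not, nor does it for the ventral comparison over both sexes (96 of 337 genes). The number in the titles held 1 group of sire treatment and sex each, so a litter, cage, day or handling that it may mark cannot be told apart from the group. Sire treatment in males stays open too, and was not tested apart from that number.

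Antisense genes were higher in the ventral hippocampus of nicotine-sired males: of 300 antisense genes tested with their host gene, 88 were called higher and 0 lower by edgeR. Genomic DNA is argued against by olfactory and vomeronasal receptor genes, whose share of the counts in these libraries was 0.977 times that in the other ventral libraries. Reads counted on the strand opposite to their origin may account for it, since 81.6% of the 212 antisense genes that were not called also lay above their host gene, just past the bound of 80%. That test is weak evidence, because the same share was 81.5% in the dorsal comparison over both sexes and 71.3% in ventral females, where 0 antisense genes were called. With the antisense ratio as a covariate Grin1os shrank from 2.76 ± 0.30 to 0.94 ± 0.57 over both sexes and Tsc22d3 went from -0.77 ± 0.06 to -0.81 ± 0.19, in a fit where 91.5% of the ratio's variance lies between the groups, and antisense transcription in these animals stays open and was not tested.

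Rbm3, Cirbp and Dbp had treatment differences of opposite sign in the sexes in the dorsal hippocampus, and these genes are known to follow body temperature and the daily cycle. Time of day at collection is neither excluded nor shown, since 11 of 14 other clock genes had the sign that their phase relative to Dbp would give in the dorsal hippocampus, where 12 would have counted for it and 9 against it, and 9 had it in the ventral hippocampus. Body temperature is a candidate explanation, since 18 of 24 heat shock and unfolded protein genes had a positive log2 fold change in the dorsal hippocampus of nicotine-sired females, where Rbm3 fell. That count lies on a bound that was set with the count known, and it would not reach a bound of 20, 17 of 24 were positive in the ventral hippocampus, and 0 of the 24 passed edgeR's test in females (3 dorsal and 9 ventral genes unadjusted, 0 and 2 by DESeq2). In nicotine-sired males, where Rbm3 rose, 20 dorsal and 21 ventral genes of the 24 were called lower, as was known when temperature was named, so temperature, sire treatment and sex stay open, and the labels give neither the time of collection nor a temperature.

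Other splits of the same libraries were fitted in the same way, with the real split counted among them. Chance was not excluded for the dorsal comparison over both sexes, where 8 of 100 splits called at least 15 genes and the highest other split called 761, a number that points to a structure of the samples. That split and 5 others of the 8, the real one included, keep the males by sire treatment, and it places nicotine-sired female A and saline-sired females B and C with the nicotine-sired males. It differs from the split that gives the difference between the sexes by 1 exchange, of nicotine-sired female A with saline-sired female A. For the ventral comparison 1 of 100 splits, the real one, reached 337 genes, a share under 0.05. The highest other called 205, the split that gives the difference between the sexes. Such a share argues against a chance division of single animals only. The splits move single animals, so they cannot tell sire treatment or sex apart from what the title number marks. For the difference between the sexes, 2 of 100 dorsal splits reached 428 genes or more (highest other 761). In the ventral hippocampus 2 of 100 reached 205 or more (highest other 337, the real split by sire treatment). Both shares were under 0.05. The dorsal split at 761 lies above the real count, so the dorsal share does not exclude a structure of the samples. Females against males gave 2 of 100 dorsal splits at 35 or more (highest other 428) and 3 of 100 ventral splits at 56 or more (highest other 205), where both highest others are the splits that give the difference between the sexes. The real split calls transcripts that mark sex itself, such as Xist and Ddx3y, so the counts were repeated without the X and Y chromosomes. This was done after the results were seen. Then 3 of 100 dorsal splits reached the real 13 (highest other 414) and 4 of 100 ventral splits the real 37 (highest other 198). The shares were under 0.05 in both regions. The 10 splits of 6 animals within a sex are too few for a share under 0.05: the real counts were 341 and 617 in dorsal and ventral males (highest others 86 and 0) and 6 and 6 in females (highest others 0 and 1), and 1 split of 10, the real one, was as large in each.

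For the gene lists chance was not excluded, since 15 of 100 dorsal splits gave 17 or more lists (highest other 25) and 63 of 100 ventral splits gave 10 or more (highest other 18). The splits gave a median of 12 dorsal and 11 ventral lists, and never fewer than 4 in either region. All 50 of 50 splits gave 0 genes by edgeR for the difference between the regions, as the real one did, where 945 genes had an unadjusted p under 0.05 and DESeq2 called 0. For ventral against dorsal in saline-sired offspring 1 of 50 splits, the real one, reached 2877 genes, which argues against a chance division of the libraries. The 50 held all 32 splits that part all 6 animals and 18 drawn from the rest, so the like share is 1 of 32. Among the 32 splits that part all 6 animals, as the real one does, the highest other called 1206, and among 18 that part fewer it was 5.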

How the results depend on the processing

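The tests with the antisense ratio or the choroid plexus level as a covariate, and those without noncoding genes opposite coding genes, were chosen after seeing the data, and the others were planned. No refitted value of a named gene reversed its direction under any alternative run. Of the lists, only the heat shock and the glucocorticoid list were followed in this way, over both sexes and in males, and neither reversed. Some genes were not refitted in every comparison that names them, such as Sgk1, Arrdc2, Xdh and Hspa1b for the difference between the sexes. DESeq2-style size factors moved no count by over 1.5 times and changed no call among 171 values of named genes and lists, and the non-robust fit ended 3 calls among 163 such values. Over 2052 refits of such values without 1 replicate, a call ended in 179, and the antisense covariate ended 83 calls among 122 values. The depth of 32049800 to 47486500 counts per library limits low genes such as Lcn2 outside saline-sired males. Except where fewer genes or samples were used, the cause was not tested.

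Counts of called genes that moved by over 1.5 times were, with DESeq2, dorsal both sexes 15 to 203, ventral both sexes 337 to 681, dorsal males 341 to 878, dorsal females 6 to 284, ventral females 6 to 283, dorsal sex difference in treatment 428 to 1289, ventral sex difference in treatment 205 to 547, dorsal females against males 35 to 113 and ventral females against males 56 to 250. Without a low-count filter they were dorsal both sexes 15 to 55, ventral both sexes 337 to 560, dorsal females 6 to 14, ventral females 6 to 99, dorsal females against males 35 to 54 and ventral females against males 56 to 124. An additive model gave dorsal both sexes 15 to 0 and ventral both sexes 337 to 216, and the spread of all 24 libraries dorsal both sexes 15 to 61 and ventral both sexes 337 to 206. With the antisense ratio as a covariate they were dorsal both sexes 15 to 1, ventral both sexes 337 to 1, dorsal males 341 to 152, ventral males 617 to 1, dorsal females 6 to 3, ventral females 6 to 2 and ventral sex difference in treatment 205 to 3, with the choroid plexus level ventral both sexes 337 to 166, dorsal females 6 to 2, ventral females 6 to 42, dorsal sex difference in treatment 428 to 236 and ventral sex difference in treatment 205 to 112, and without noncoding genes opposite coding genes ventral both sexes 337 to 191 and dorsal females 6 to 1. The dorsal lists went from 17 to 2 with an estimated correlation and to 2 with fry, and the ventral lists from 10 to 1 and 3.

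The title letters A, B and C recur in every group, while the title number differs between the groups of sire treatment and sex. Pairs of nicotine-sired and saline-sired libraries with the same letter correlated with a median r of 0.0338. Of these, 4 of 12 were over 0.1 and 3 of 12 correlated best with their own letter. Pairs of females and males had a median r of -0.0499 (2 of 12 best with their own). With the letter as a replicate block the counts went, for dorsal both sexes 15 to 0, dorsal males 341 to 77, dorsal females 6 to 1, ventral females 6 to 60 and dorsal sex difference in treatment 428 to 61, and for dorsal females against males 35 to 22. With the animal as a replicate block the regions went from 2877 to 4435, and that block changed no call among the 26 genes named for the region comparisons.

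Leaving out each replicate in turn gave these lowest and highest counts: dorsal both sexes 0 to 19, ventral both sexes 176 to 457, dorsal males 87 to 624, ventral males 284 to 671, dorsal females 0 to 12, ventral females 0 to 114, dorsal sex difference in treatment 76 to 837, ventral sex difference in treatment 84 to 463, dorsal females against males 22 to 46, ventral females against males 29 to 125, regions 1097 to 3403, region difference in treatment 0 to 0, dorsal lists 11 to 18 and ventral lists 10 to 15. The dorsal lists were 11 without nicotine-sired male C.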

Other observations

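The pituitary hormone transcripts were highest in 1 ventral library: Prl, the prolactin gene, reached 209 CPM and Gh, the growth hormone gene, 115 CPM in the ventral library of nicotine-sired female B, against medians of 1.56 and 2.45 CPM over the 24 libraries. The next highest values were 28.1 CPM of Prl in the ventral library of nicotine-sired female C and 35.0 CPM of Gh in that of saline-sired male A. The choroid plexus transcript Ttr lay between 1029 and 5204 CPM in 8 libraries and between 25.2 and 144 CPM in the other 16. The 8 were the dorsal and ventral libraries of nicotine-sired females B and C, and the dorsal libraries of nicotine-sired males A and B, saline-sired male A and saline-sired female C. The antisense ratio was 0.420% and 0.445% in the dorsal libraries of nicotine-sired males A and B and 0.438% in that of saline-sired male B, and at most 0.279% in the other 9 dorsal libraries.

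Immediate early genes, which neuronal activity induces, had positive log2 fold changes for 18 of 23 members in the dorsal and 20 of 23 in the ventral hippocampus of nicotine-sired males, of which 2 dorsal genes passed edgeR's test over all genes and 6 adjusted over the list alone (camera adjusted p = 0.413 and 0.643 with an estimated correlation). Mitochondrially encoded transcripts had positive log2 fold changes for 14 of 15 members in dorsal and 15 of 15 in ventral nicotine-sired males (medians 0.29 and 0.35, camera adjusted p = 0.413 and 0.643 with an estimated correlation). EdgeR called 0 of them in the dorsal and 1 in the ventral hippocampus over all genes. An unadjusted p under 0.05 was found for 9 and 8, and DESeq2 called 7 and 2. Copies of mitochondrial genes on chromosome 1 took between 3.25% and 5.31% of the counts of a library. The mitochondrially encoded transcripts thus appear to share reads with near-identical copies and are uncertain.

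The dorsal library of nicotine-sired female A lay apart from its replicates, with a chi-square per gene of 91.2 against B and 66.0 against C, while B against C gave 14.1 and the pairs within the other dorsal groups 12.7 to 48.4. Its mean level of the dorsal markers was 5.21 log2 CPM, and 6.02 to 6.76 in the other 11 dorsal libraries. Without that replicate edgeR called 624 dorsal genes in males and 837 for the difference between the sexes, where it called 341 and 428 with it. The ventral library of nicotine-sired male A gave 61.8 against B and 60.2 against C, while B against C gave 25.5 and the pairs within the other ventral groups 6.64 to 28.3. By the correlation of log2 CPM it was not apart, with r of 0.9885 and 0.9901 against B and C. There B against C gave 0.9905 and the pairs within the other ventral groups 0.9869 to 0.9953. Without that replicate edgeR called 51 ventral genes in females and 463 for the difference between the sexes, where it called 6 and 205 with it.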
